A study of Mus musculus with 12 samples.

How the data were processed

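RNA from mouse hearts was measured in 12 libraries in 4 groups of 3, defined by strain (Balb/cJ or Balb/cByJ) and by surgery (sham or transverse aortic constriction, TAC). Libraries were made with a stranded mRNA kit from total RNA and read on a NextSeq 500, per the labels' protocols and the series' design text. Reads were aligned with STAR, counted per gene with featureCounts of the Subread package and analysed with DESeq2 against the mouse genome build mm10, per the submitters' processing notes. The versions, the counting's strand setting and the gene annotation release are not given in the sources used here. Genes that overlap on opposite strands, and near-identical copies such as Hba-a1 and Hba-a2, can therefore share reads, and their values are uncertain.

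The deposited table held 27179 genes, with a value per gene and library, the gene's position and length, and the authors' results for TAC against sham in each strain. Gene values were deposited as scores, namely read counts that the authors had divided by a size factor per library and rounded to whole numbers. This reading rests on the values themselves: in some libraries evenly spaced whole numbers never occurred, and in others they occurred too often, as such a division leaves. The size factors recovered from that spacing ran from 0.85 to 1.24, which puts the estimated reads assigned to genes between 25.9 and 35.8 (in units of 1000000) per library. On simulated values the same recovery erred by at most 0.0011. Rounding prevents an exact return to counts, so no count model was used. The deposited log2 fold changes were shrunken by the authors' method, per the file headers. The deposited adjusted p-values carried the 10% false discovery rate of the series' design text, and a gene without such a p-value was left without one. Of the gene entries, 847 carried no symbol. Gene lengths, deposited in another unit (bases of summed exons, per the file headers), were not used.

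Columns of the sham libraries carried the titles' numbers. The TAC columns were numbered differently from the TAC titles, so each was assigned to its group by strain and surgery only, under the number in its column name (4, 5 or 6). The p-values measure the spread between these libraries.

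The design fixed before the data were examined foresaw a quasi-likelihood test on counts, or limma if the values proved to be normalized. The second case applied. Values were transformed as log2(value + 1), where 1 is the pseudocount, and genes with a mean of at least 10 over all libraries were kept (14038 of 20278 genes with any value above 0). A mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (eBayes with a trend), which left 8 residual degrees of freedom. The 5 contrasts were TAC against sham in each strain, Balb/cByJ against Balb/cJ after each surgery, and the strain by surgery interaction, coded as the TAC effect in Balb/cByJ minus that in Balb/cJ. A gene passed at a Benjamini-Hochberg adjusted p under 0.1. Log2 fold changes are given with standard errors (SE) on the log2(value + 1) scale, which understates the change of genes with low values.

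Gene lists (36 lists with 997 genes, of which 982 matched) were also written before the data were examined, and 34 had at least 3 measured members. They cover heart stress, contraction, matrix, energy metabolism, proliferation, inflammation and markers of the cell types that a dissected heart can hold. Each list was tested with camera at a preset correlation of 0.01 and adjusted over the lists within a comparison, and again with an estimated correlation and with fry. List members were counted as passing both over all genes tested and adjusted over the list alone. Genes were named by a rule, which took genes with a mean of at least 50 whose groups of libraries did not overlap. From these it took the 12 with the largest rise and the 12 with the largest fall that passed, leaving out predicted genes. Acads and up to 4 members per list, in order of the smallest p, were added. Any other gene is said to have been chosen after its values were seen.

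The alternatives planned beforehand were no filter on low values, pseudocounts of 0.5 and 5, an adjusted p of 0.05, upper-quartile rescaling, voom on approximate reads, a fit of only the groups compared, a replicate block for the sham libraries, and leaving out each library. The count models planned and their scalings were not run because the values were not counts. Rescaling each library to the same total, covariates for atrial genes on a log or linear scale, and a replicate block by column number for the TAC libraries, were added after the data were seen. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

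The fit was tested on simulated libraries with 14038 genes, a few of which were changed by a known size. Each gene was given its mean over all 12 libraries and its spread within groups. Genes were drawn independently of one another, so the correlation between real genes was left out. For TAC against sham in Balb/cJ it recovered 34.3% of the 67 genes changed 1.5-fold, 62.7% of the 67 changed 2-fold and 87.9% of the 66 changed 4-fold, with 7.52% false calls. For TAC against sham in Balb/cByJ it recovered 31.3%, 73.1% and 92.4% at the same sizes, with 7.75% false calls. For the strains after sham the shares were 32.8%, 73.1% and 95.5%, with 10.1% false calls. For the strains after TAC they were 43.3%, 67.2% and 87.9%, with 10.2% false calls. These shares hold for few changed genes, where the adjusted p is stricter than with many.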

Results

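Hearts of Balb/cJ mice and of Balb/cByJ mice, a substrain that carries a deletion in Acads, were compared after sham surgery or transverse aortic constriction (TAC), which narrows the aorta and loads the left ventricle with pressure. Mice ate a diet with 10 kcal% fat from 4 days before surgery, and hearts were taken 1 week after it. Each of the 4 groups held 3 libraries. Sums of the normalized gene values per library ran from 28979605 to 34157613 in sham Balb/cJ, 25161466 to 28765635 in TAC Balb/cJ, 27790037 to 31092208 in sham Balb/cByJ and 26157968 to 26989827 in TAC Balb/cByJ. Within groups, libraries correlated at r = 0.974 to 0.988 across genes, which are not independent replicates. Mitochondrially encoded transcripts took 10.75 to 17.24% of a library's sum. All libraries held Y-linked transcripts (Ddx3y 667 to 1529) and almost no Xist (0 to 3), so sex did not differ between the groups.

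Acads, which encodes short-chain acyl-CoA dehydrogenase of mitochondrial fatty acid oxidation, was read first as a check of the strain labels. The gene (Entrez 11409) lies on chromosome 5 at 115110299 to 115119313 on the minus strand of mm10, with 10 exons in the deposited annotation. Its normalized values were 9033, 10928 and 10628 in sham Balb/cJ libraries 1 to 3 (mean 10196 ± 1020, SD, n = 3) and 8670, 7252 and 5415 in TAC Balb/cJ libraries 4 to 6 (7112 ± 1630). They were 6929, 6234 and 6925 in sham Balb/cByJ libraries 1 to 3 (6696 ± 400) and 5674, 5613 and 6697 in the libraries labelled TAC Balb/cByJ 4 to 6 (5995 ± 609). Acads RNA was thus present in both strains, and a sum over the whole gene cannot show whether the deleted part is missing. The libraries labelled TAC Balb/cByJ lay within the TAC Balb/cJ range (5415 to 8670), so Acads could not check the label of a single TAC library. The difference between the strains after sham was -0.60 ± 0.15 on the log2 scale (limma adjusted p = 0.0453), and after TAC it was -0.22 ± 0.15 (adjusted p = 0.663). Acads fell after TAC in Balb/cJ (-0.54 ± 0.15, adjusted p = 0.0274), its difference in Balb/cByJ (-0.16 ± 0.15, adjusted p = 0.501) did not pass, and the interaction of 0.38 ± 0.21 did not pass (adjusted p = 0.748). The fall in Balb/cJ did not pass without sham Balb/cJ 2 (-0.49). The strain difference after sham did not pass without sham Balb/cJ 2 (-0.55), sham Balb/cJ 3 (-0.57) or sham Balb/cByJ 2 (-0.55), nor did either value with the log-scale atrial covariate (-0.40 and -0.48). With total rescaling the differences for TAC were -0.33 in Balb/cJ, which passed, and 0.00 in Balb/cByJ. Without TAC Balb/cJ 6 the fall in Balb/cJ was -0.36, the strain difference after TAC -0.41 and the interaction 0.20, and without TAC Balb/cJ 4 the strain difference after TAC was -0.07.

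Strain labels were read at other genes as well. Zhx2, a transcriptional repressor known to differ among BALB/c substrains, lay at 21 to 47 in the Balb/cJ libraries and at 728 to 838 in 5 Balb/cByJ libraries, but at 48 in the library labelled TAC Balb/cByJ 6. Dnah17, an axonemal dynein gene chosen after its values were seen in this library, lay at 805 to 1019 in those 5 libraries and at 2 in the library labelled TAC Balb/cByJ 6. Every result that uses the TAC Balb/cByJ group includes this library as labelled, and counts of genes without it are given beside the counts.

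**Figure D1:**
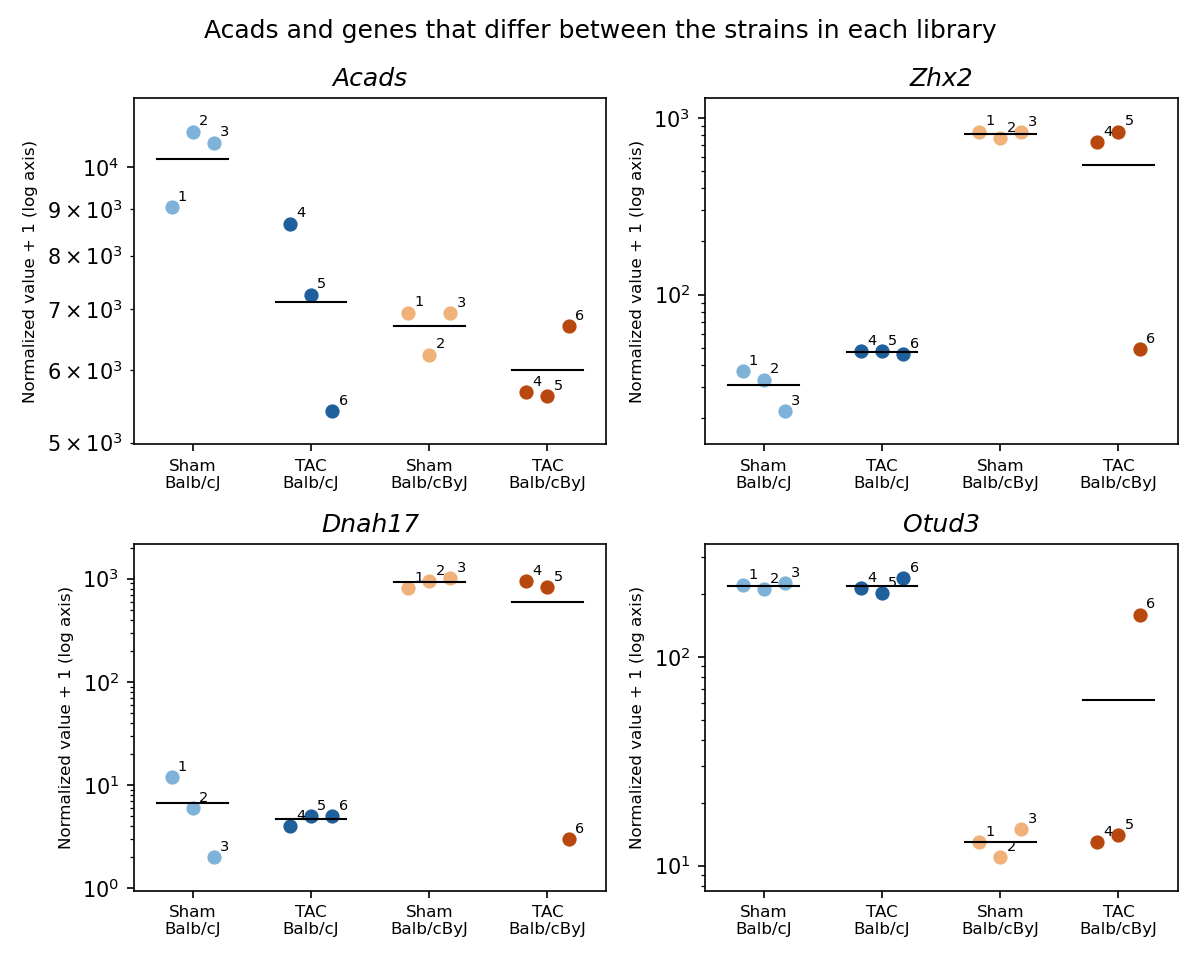
Normalized value + 1 on a log axis of Acads, Zhx2, Dnah17 and Otud3 in each of the 12 libraries, by group, with library numbers beside the points and group means as lines. The library labelled TAC Balb/cByJ 6 lies at 48 for Zhx2 and 2 for Dnah17, apart from the other Balb/cByJ libraries.

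**Figure D2:**
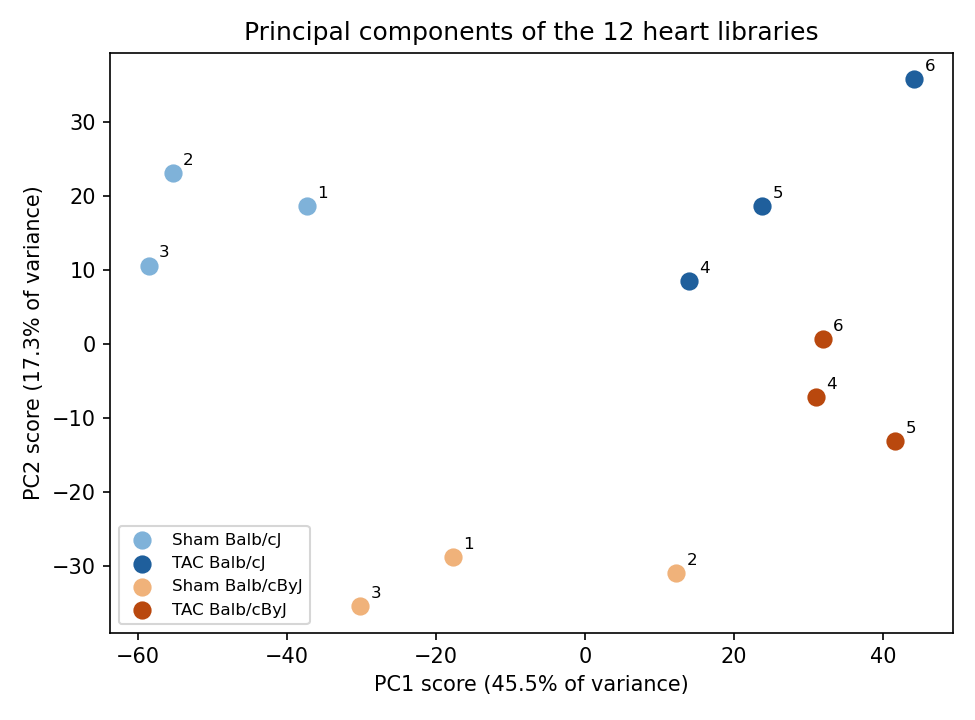
Scores of the 12 libraries on the first principal components of log2(value + 1), with library numbers beside the points and colours for the 4 groups. The first component held 45.5% of the variance and the second 17.3%; sham Balb/cJ libraries lie from -58.5 to -37.3 on the first, sham Balb/cByJ libraries from -30.1 to 12.3, and all TAC libraries from 14 to 44.2.

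The effect of pressure load in Balb/cJ hearts, the strain without the Acads deletion, was broad. Genes of the extracellular matrix rose most uniformly: Timp1, an inhibitor of matrix metalloproteinases, rose by 3.28 ± 0.34 on the log2 scale and Col12a1 by 4.16 ± 0.43 (limma adjusted p = 0.000775 for both, n = 3 per group). Fmod, a collagen-binding proteoglycan, rose by 5.67 ± 0.53 from 8 to 17 in the sham Balb/cJ libraries, but it was at 339 to 1017 in sham Balb/cByJ and did not pass for TAC there (0.64 ± 0.53, adjusted p = 0.455), so its rise started from low values in sham Balb/cJ. Genes of cell division and of macrophages rose with them. Genes of oxidative phosphorylation and fatty acid oxidation fell by smaller amounts. The largest rises among the named genes were those of the atrial genes Sln (9.45 ± 1.6) and Myl7 (9.38 ± 1.48), which were nearly absent from the sham Balb/cJ libraries.

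Of 63 measured matrix and fibrosis genes, 60 rose, 0 fell and 3 did not pass (median log2 1.76; 60 rose adjusted over the list alone). Cell cycle genes rose in 37 of 43 members (38 adjusted over the list alone), among them the mitotic kinases Aurkb (2.53 ± 0.36) and Cdk1 (2.78 ± 0.46). Of 29 macrophage and monocyte markers, 23 rose (25 adjusted over the list alone), with Ccr2, the chemokine receptor of infiltrating monocytes, at 3.92 ± 0.44 and the mannose receptor Mrc1 at 1.48 ± 0.21. Cytokine and acute inflammation genes rose in 25 of 36 members and fell in 1 (28 and 1 adjusted over the list alone), including Ccl2, the ligand of Ccr2 (2.42 ± 0.32), and the adhesion molecule Selp (2.35 ± 0.36). Fibroblast markers rose in 15 of 20 members (16 adjusted over the list alone), with Col3a1 at 2.43 ± 0.36. These lists passed camera with adjusted p = 1.92e-31, 2.02e-17, 1.81e-13, 8.94e-10 and 4.51e-07 in this order. None passed with an estimated correlation (adjusted p = 0.297, 0.298, 0.297, 0.252 and 0.298 with an estimated correlation). Fry, which tests whether a list moves on balance in a single direction, gave adjusted p = 0.00371, 0.0059, 0.0046, 0.00169 and 0.00518.

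Markers of tissues beside the ventricular wall moved with these groups. Atrial and conduction markers rose in 8 of 13 members (10 adjusted over the list alone; median log2 2.58). Myl7, the atrial myosin light chain, was at 6 to 13 in sham Balb/cJ, 2381 to 15126 in TAC Balb/cJ, 237 to 14508 in sham Balb/cByJ and 640 to 30930 in TAC Balb/cByJ. Adipocyte markers rose in 9 of 10 members (9 adjusted over the list alone; median 4.34), among them Cfd (5.54 ± 1.07), Cidec (5.17 ± 1.04) and Adipoq (4.55 ± 0.97). Epicardial and mesothelial markers rose in 8 of 11 members (9 adjusted over the list alone; median 2.11), with Upk3b at 3.91 ± 0.40. Camera gave adjusted p = 7.78e-06, 1.91e-05 and 4.11e-06 for these lists, and adjusted p = 0.432, 0.432 and 0.252 with an estimated correlation. With the mean log2 level of 3 atrial genes as a covariate, the medians of the atrial and adipocyte lists turned to -0.83 and -0.16, and those of Bmp10, Hamp, Myl4, Cidec and Adipoq turned to -2.36, -2.01, -1.40, -0.14 and -0.12. Other named rises were those of Hamp, which encodes hepcidin (6.71 ± 1.59), Bmp10 (7.18 ± 2.18), Myl4 (6.46 ± 1.38), Clec3a (6.33 ± 0.91), Car3 (6.03 ± 1.02), Cyp2e1 (5.70 ± 1.00) and the fibrillar collagen Col11a1 (5.25 ± 0.99). Of the genes named for their rises in Balb/cJ, Fmod (5.43), Col12a1 (1.37), Ccr2 (2.00), Upk3b (3.52), Hamp (5.73), Myl4 (5.32), Clec3a (5.35), Car3 (3.23), Sln (8.18) and Myl7 (7.90) were also higher in sham Balb/cByJ than in sham Balb/cJ at an adjusted p under 0.1, so these rises started from sham values below those of the other strain.

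**Figure D3:**
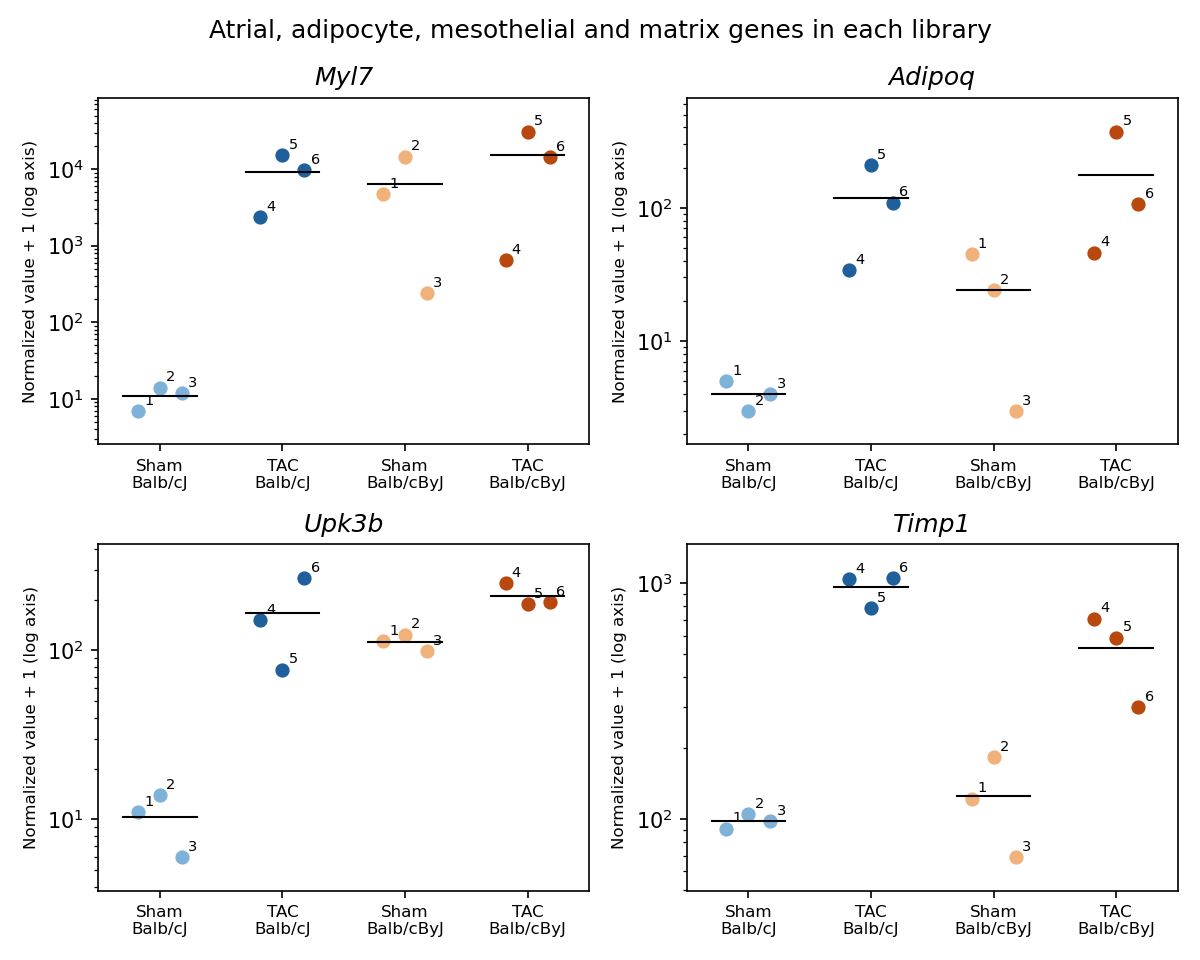
Normalized value + 1 on a log axis of the atrial gene Myl7, the adipocyte gene Adipoq, the mesothelial gene Upk3b and the matrix gene Timp1 in each of the 12 libraries, by group, with library numbers and group means as lines. Myl7 lies at 6 to 13 in sham Balb/cJ and ranges from 237 to 14508 among the sham Balb/cByJ libraries.

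Energy metabolism genes fell in the same hearts. Nuclear subunits of oxidative phosphorylation fell in 66 of 77 members (75 adjusted over the list alone; median -0.55), with the cytochrome oxidase subunit Cox8b at -0.93 ± 0.19 and Uqcrq of complex III at -0.79 ± 0.18. Mitochondrial fatty acid oxidation genes fell in 22 of 31 members (27 adjusted over the list alone; median -0.53), such as Etfb, an electron acceptor of the acyl-CoA dehydrogenases (-0.92 ± 0.24), and Acot13 (-0.69 ± 0.16). Tricarboxylic acid cycle genes fell in 17 of 33 members (21 fell and 1 rose adjusted over the list alone; median -0.37), including Pdk2, a kinase of pyruvate dehydrogenase (-0.59 ± 0.14). Ribosomal protein genes fell in 49 of 76 members (62 adjusted over the list alone; median -0.30). Endothelial markers fell in 12 of 22 members and rose in 2 (13 and 2 adjusted over the list alone; median -0.50), with Esam at -0.58 ± 0.11 and Robo4 at -0.61 ± 0.13. Camera gave adjusted p = 3.88e-20, 4.07e-08, 1.56e-06, 5.02e-13 and 0.00118. With an estimated correlation none passed (adjusted p = 0.496, 0.528, 0.528, 0.528 and 0.436 with an estimated correlation). Atrial and adipocyte markers went the other way in this comparison and rose, at the medians given above.

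Heart muscle genes moved in both directions. Cardiac stress and fetal genes rose in 13 of 28 members (16 adjusted over the list alone; median 0.64; camera adjusted p = 7.58e-06, and adjusted p = 0.252 with an estimated correlation). Fhl1, a LIM protein of the stretched sarcomere, rose by 1.94 ± 0.23 and the proteoglycan Vcan by 1.81 ± 0.23. Other genes of heart stress, chosen after their values were seen, differed among themselves. Nppb had means of 19343 in sham and 14875 in TAC Balb/cJ, and of 11036 and 12201 in sham and TAC Balb/cByJ. Myh7 had means of 61783 in sham and 68211 in TAC Balb/cJ. Nppa, also among the atrial markers, had means of 13027 and 86140 there. Adult contraction and calcium handling genes fell in 13 of 37 members and rose in 3 (13 and 4 adjusted over the list alone), with the potassium channel subunits Kcnip2 at -0.70 ± 0.17 and Kcnj11 at -0.44 ± 0.09. Their median was -0.16, turned to 0.05 with total rescaling and was -0.01 with the log-scale atrial covariate; camera gave adjusted p = 0.0524, and adjusted p = 0.543 with an estimated correlation. Falls included those of Aqp6 (-2.18 ± 0.65), Gnb3 (-2.02 ± 0.40), Plekhh1 (-1.85 ± 0.45), Timp4, an inhibitor of metalloproteinases abundant in heart (-1.62 ± 0.33), and Rgcc (-1.54 ± 0.39). ND6, which mitochondria encode on the strand opposite most of their genes, fell by 1.72 ± 0.39.

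In all, 4419 of 14038 genes passed in Balb/cJ, 2146 higher and 2273 lower after TAC, and 899 of the former and 140 of the latter differed more than 2-fold. The groups of libraries did not overlap at 36.9% of all genes, where chance gives 10%. The authors' deposited table called 1850 genes higher and 1542 lower, and 3141 of its calls were shared with limma in direction. With each library rescaled to the same total the median gene moved by 0.21 and the split became 3936 higher and 891 lower. Leaving out sham Balb/cJ 2, sham Balb/cJ 3 or TAC Balb/cJ 6 left 2188, 2609 and 2156 genes, and the log-scale atrial covariate left 0 by limma (1431 at an unadjusted p under 0.05), against 3146 with the linear covariate.

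**Figure D4:**
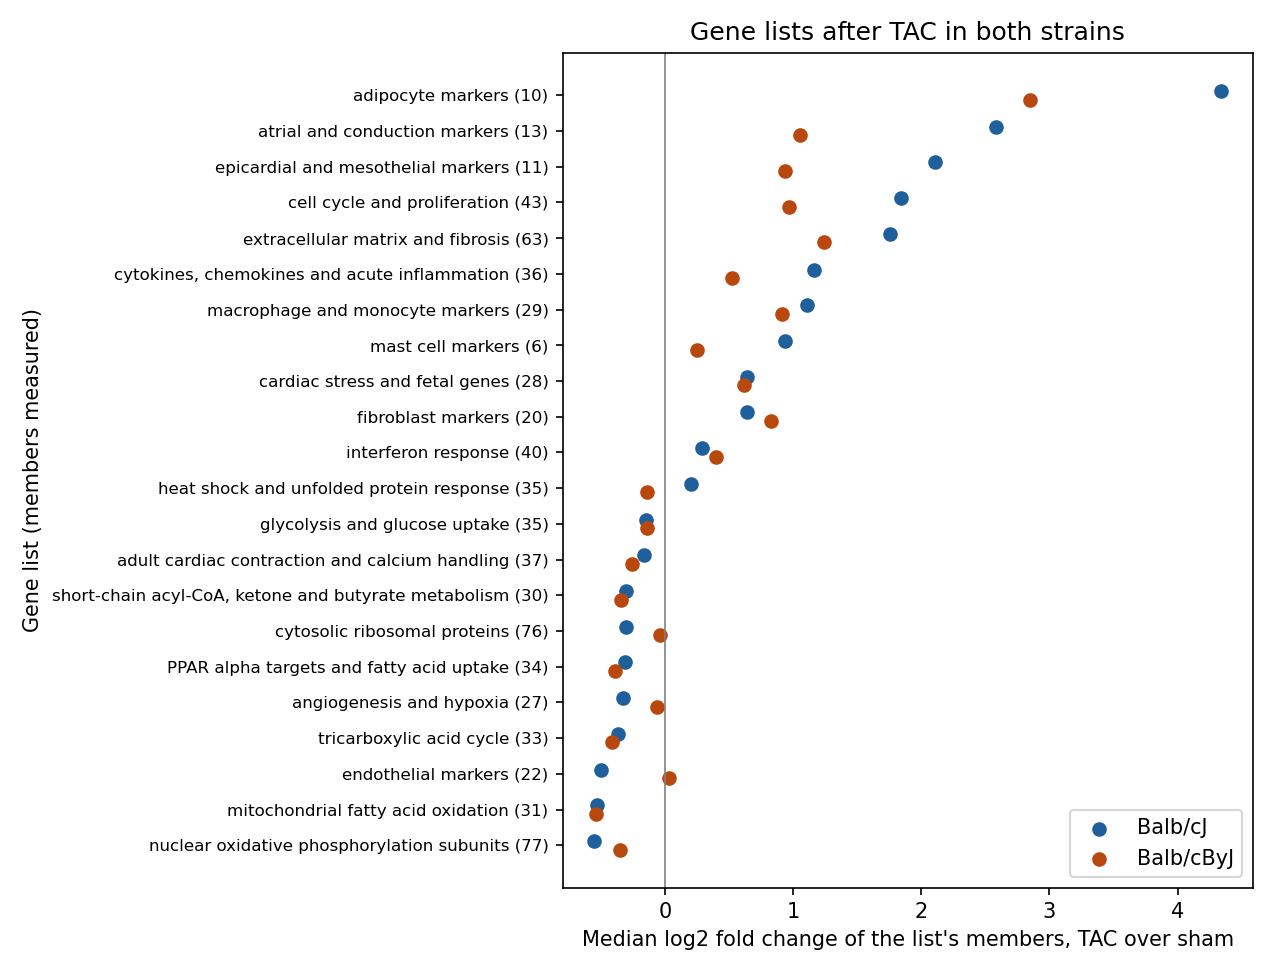
Median log2 fold change of TAC over sham for the 22 gene lists that passed camera in Balb/cJ, with the number of measured members in brackets, in Balb/cJ (blue) and Balb/cByJ (orange). None of these lists passed with an estimated correlation. The matrix list lies at 1.76 and 1.24 and the fatty acid oxidation list at -0.53 and -0.54; with total rescaling the glycolysis list turned to 0.06 and 0.01, the contraction list to 0.05 in Balb/cJ, and the angiogenesis, ribosomal and heat shock lists in Balb/cByJ to 0.10, 0.12 and 0.01.

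Hearts labelled Balb/cByJ, the substrain with the Acads deletion per the series' title, were compared in the same way. Matrix genes rose again, with elastin (Eln) at 2.01 ± 0.30 and Timp1 at 2.11 ± 0.34 (limma adjusted p = 0.0181 and 0.0194, n = 3 per group). Fibroblast and macrophage genes rose, and genes of fatty acid oxidation and the tricarboxylic acid cycle fell. The antibody light chain gene Igkc rose by 2.42 ± 0.50. The beta myosin heavy chain Myh7, a fetal heart gene, rose by 0.85 ± 0.16. Its sham Balb/cByJ values (43079 to 47958) lay below those of sham Balb/cJ (57297 to 69371), so this rise started from lower values.

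Among matrix and fibrosis genes 51 of 63 rose and 12 did not pass (55 rose adjusted over the list alone; median 1.24). Fibroblast markers rose in 16 of 20 members (18 adjusted over the list alone), with Pi16 at 1.36 ± 0.16 and Col3a1 at 2.08 ± 0.36. Macrophage markers rose in 18 of 29 members (23 adjusted over the list alone), among them the integrin Itgam (1.48 ± 0.22) and Mrc1 (1.28 ± 0.21). Cytokine and inflammation genes rose in 9 of 36 members (13 adjusted over the list alone), with the acute-phase gene Saa3 at 4.07 ± 0.71 and the oncostatin M receptor Osmr at 0.75 ± 0.15. Cell cycle genes rose in 4 of 43 members (15 adjusted over the list alone), such as Cdca8 (1.28 ± 0.32). Lymphocyte markers rose in 3 of 11 members (4 adjusted over the list alone), and these were Ighm (1.57 ± 0.24), Igkc and Jchain (1.89 ± 0.62), which encode antibody chains. Camera gave adjusted p = 4.01e-29, 7.07e-13, 1.08e-11, 5.95e-06, 4.18e-07 and 0.02 for these lists. None passed with an estimated correlation (adjusted p = 0.375, 0.375, 0.399, 0.375, 0.442 and 0.41 with an estimated correlation). Fry gave adjusted p = 0.0215, 0.00816, 0.0215, 0.0215, 0.122 and 0.0215, so the cell cycle list did not pass it. Adipocyte markers moved with them, rising in 6 of 10 members (9 rose and 1 fell adjusted over the list alone; median 2.85), while 0 of 13 atrial markers passed by limma (median 1.05). Adipocyte and atrial lists passed camera at adjusted p = 0.00063 and 0.0955, with adjusted p = 0.442 and 0.663 with an estimated correlation, and the atrial median turned to -0.36 with the linear covariate. Neither list passed fry (adjusted p = 0.121 and 0.465).

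Fatty acid oxidation genes fell in 14 of 31 members (29 adjusted over the list alone; median -0.54), with Acad9 at -0.41 ± 0.09 and the methylmalonyl-CoA mutase gene Mut at -0.47 ± 0.12. Tricarboxylic acid cycle genes fell in 11 of 33 members (27 adjusted over the list alone; median -0.41), with Suclg2 at -0.57 ± 0.13. Genes of short-chain acyl-CoA and ketone metabolism fell in 13 of 30 members (16 fell and 2 rose adjusted over the list alone; median -0.34), among them Oxct1, which activates ketone bodies (-0.50 ± 0.13). Subunits of oxidative phosphorylation fell in 6 of 77 members (0 by limma adjusted over the list alone; median -0.35), with Ndufs1 of complex I at -0.47 ± 0.12. Contraction genes fell in 5 of 37 members (7 adjusted over the list alone), with Kcnip2 at -0.70 ± 0.17. Stress and fetal genes rose in 8 of 28 members (15 rose and 1 fell adjusted over the list alone), with Fhl1 at 1.49 ± 0.23. Camera gave adjusted p = 1.01e-11, 1.01e-11, 1.81e-06, 6.58e-14, 6.44e-05 and 2.43e-05. With an estimated correlation none passed (adjusted p = 0.41, 0.41, 0.41, 0.478, 0.41 and 0.375 with an estimated correlation). Fry gave adjusted p = 0.074, 0.047, 0.0583, 0.158, 0.0356 and 0.0215, so the oxidative phosphorylation list did not pass it.

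Other rises in Balb/cByJ included those of the tubulin gene Tubb3 (4.20 ± 0.69), the adipocyte genes Cfd (3.41 ± 1.07) and Cidec (3.36 ± 1.04), haptoglobin (Hp, 3.22 ± 0.67) and the collagen gene Col22a1 (3.20 ± 0.49), with Tnc (2.62 ± 0.49), Cilp (2.64 ± 0.46) and Cthrc1 (2.58 ± 0.69) of the matrix. Between the sham groups Col22a1 (-3.21, limma adjusted p = 0.00627) and Hp (-2.74, adjusted p = 0.0429) were lower in Balb/cByJ. The rises of these 2 genes thus started from sham values below those of the other strain. Aqp6 (-2.10 ± 0.65), Scd4 (-1.96 ± 0.61), Plekhh1 (-1.69 ± 0.45) and Gnb3 (-1.46 ± 0.40) were among the falls. Scd4 fell from a sham mean of 1008, where sham Balb/cJ had a mean of 119. In all, 1765 genes passed, 1097 higher and 668 lower after TAC, of which 418 and 15 differed more than 2-fold. The authors' deposited table called 1537 genes higher and 1463 lower, and 1655 of its calls were shared. Rescaling to the same total moved the median gene by 0.15 and gave 1634 higher and 228 lower. The count fell to 6 without sham Balb/cByJ 1, 75 without sham Balb/cByJ 3, 515 without TAC Balb/cByJ 4, 469 without TAC Balb/cByJ 5, and 687 without the library labelled TAC Balb/cByJ 6. Without that library 19 lists passed camera, and members passed in fewer numbers: 46 matrix, 13 fibroblast, 14 macrophage, 7 cytokine and 2 lymphocyte genes rose, and 1 fatty acid oxidation, 1 tricarboxylic acid cycle, 1 contraction, 0 short-chain acyl-CoA or ketone and 0 oxidative phosphorylation genes fell by limma, with 0 adipocyte markers passing, while more cell cycle (10) and stress genes (9) rose. The medians of these falling lists stayed near the first ones without it, at -0.52, -0.39, -0.30, -0.28 and -0.36 in this order, and that of the adipocyte markers at 3.02. The count of genes was 2848 in a fit of these 6 libraries alone, 694 with the log-scale and 170 with the linear atrial covariate.

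Calls in the TAC comparisons of both strains overlapped. Genes higher after TAC in both numbered 775 where independent lists of these sizes would share 168, and genes lower in both numbered 425 against 108, while 4 passed in opposite directions. Across 14038 genes the fold changes correlated at r = 0.68 and rho = 0.69, with a slope of 0.5 for Balb/cByJ on Balb/cJ. The comparisons shared no library, but both used the same spread per gene, estimated over all libraries. A gene with a small spread thus passed more easily in both, and the calls were not independent. Genes are not independent replicates, and Fisher's exact test across genes gave an odds ratio of 20.3 for the rises and 10.9 for the falls. Timp1, Fhl1, Col3a1 and Mrc1 were among the genes named as rising in both, and Aqp6, Plekhh1, Gnb3 and Kcnip2 among those falling in both. The count of shared rises was 6 without sham Balb/cByJ 1, 63 without sham Balb/cByJ 3, 298 without TAC Balb/cByJ 4, 270 without TAC Balb/cByJ 5 and 470 without the library labelled TAC Balb/cByJ 6, and that of shared falls was 0 by limma, 1, 68, 87 and 88 in this order. Shared falls also numbered 249 without sham Balb/cJ 2, 194 without sham Balb/cJ 3 and 278 without TAC Balb/cJ 5. Both counts were lower at an adjusted p under 0.05 and with either atrial covariate, as given below. Total rescaling gave more shared rises and fewer shared falls.

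Sham-operated hearts addressed what differed between the strains without pressure load. Zhx2 was higher in Balb/cByJ by 4.76 ± 0.78 on the log2 scale, Dnah17 by 7.45 ± 1.63 and the melanocyte gene Mlana by 7.71 ± 0.92 (limma adjusted p = 0.00833, 0.0279 and 0.00181, n = 3 per group). Gpnmb, a glycoprotein of macrophages and pigment cells, was higher by 4.52 ± 0.83, and the macrophage elastase Mmp12 by 7.41 ± 1.13, while the melanocyte gene Dct was lower (-2.25 ± 0.31, adjusted p = 0.0044). Otud3, a deubiquitinase gene, was lower by -4.08 ± 0.70, and Edn3, an endothelin gene, by -2.87 ± 0.41. Atrial and mesothelial genes were higher in Balb/cByJ, led by Sln (8.18 ± 1.6) and Myl7 (7.90 ± 1.48).

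Macrophage markers were higher in 5 of 29 members (6 adjusted over the list alone), with Ccr2 at 2.00 ± 0.44, and mast cell markers in 3 of 6 (4 adjusted over the list alone), with the protease gene Mcpt4 at 1.66 ± 0.42. Ribosomal protein genes were lower in 3 of 76 members (32 adjusted over the list alone; median -0.24), and glycolysis genes in 4 of 35 (5 adjusted over the list alone), with Pfkl at -0.75 ± 0.12 and Gapdh at -0.73 ± 0.15. Camera gave adjusted p = 0.00349, 0.014, 2.11e-12 and 0.00196 for these lists, and each had adjusted p = 0.771 with an estimated correlation. Beside these groups, atrial markers were higher in 6 of 13 members (7 adjusted over the list alone; median 1.67), and mesothelial markers were higher in 6 of 11 and lower in 1 (7 and 2 adjusted over the list alone), with Lrrn4 at 4.19 ± 0.46. Camera gave adjusted p = 8.85e-05 and 0.00196 for these markers, and adjusted p = 0.771 for both with an estimated correlation. Adipocyte markers were higher in 1 of 10 members (1 adjusted over the list alone; median 1.93; camera adjusted p = 0.024), and oxidative phosphorylation subunits had a median of -0.23 (camera adjusted p = 1.25e-05), with 0 of 77 passing limma, and both had adjusted p = 0.771 with an estimated correlation. With the log-scale atrial covariate the atrial and adipocyte medians turned to -0.56 and -2.15, and Hamp and Myl4 to -1.65 and -1.33.

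Targets of PPAR alpha, a regulator of fatty acid use, were higher in 2 of 34 members and lower in 1 (4 and 2 adjusted over the list alone; camera adjusted p = 0.172). Angptl4, an inhibitor of lipoprotein lipase, was higher (3.20 ± 0.83) and Gpihbp1 was lower (-0.65 ± 0.17). Of 31 fatty acid oxidation genes 0 were higher and 1, Acads itself, was lower by limma (camera adjusted p = 0.147).

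In all, 1175 genes passed between the sham groups, 599 higher and 576 lower in Balb/cByJ, with 268 and 98 beyond 2-fold. Rescaling to the same total gave 691 higher and 284 lower. The count was 321 without sham Balb/cJ 2, 623 without sham Balb/cByJ 1, 411 without sham Balb/cByJ 2, 636 without sham Balb/cByJ 3 and 35 with the log-scale atrial covariate, and lay within 1.5 times of the first count without sham Balb/cJ 1 or 3.

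After TAC, the strains differed at a single gene as labelled. Dbh, dopamine beta-hydroxylase of noradrenaline synthesis, was higher in Balb/cByJ by 1.49 ± 0.19 (limma adjusted p = 0.0535), and 1371 genes lay at an unadjusted p under 0.05. Zhx2 (2.71 ± 0.78, adjusted p = 0.289) did not pass. Of the 34 lists 11 passed camera, among them cell cycle genes (median -0.66, adjusted p = 1.25e-08, and adjusted p = 0.675 with an estimated correlation) and matrix genes (median -0.35, adjusted p = 9.46e-06, and adjusted p = 0.765 with an estimated correlation), with 0 of 43 and 0 of 63 members passing limma (0 and 5 lower adjusted over the list alone). The count depended on single libraries: it was 75 (49 higher, 26 lower; 9 lists) without the library labelled TAC Balb/cByJ 6, 61 without TAC Balb/cJ 4, 27 without TAC Balb/cByJ 4, and 0 without TAC Balb/cJ 5, TAC Balb/cJ 6 or TAC Balb/cByJ 5. Without the library labelled TAC Balb/cByJ 6 the genes that passed included Zhx2 (4.05 ± 0.20), Dnah17 (7.58 ± 0.54), Otud3 (-4.01 ± 0.20) and Glo1, an enzyme of methylglyoxal removal (1.59 ± 0.12), chosen after their values were seen.

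The interaction asked whether TAC acted differently in the strains. Prss35, a gene of the serine protease family, passed with -5.10 (limma adjusted p = 0.0627), and 954 genes lay at an unadjusted p under 0.05. Its values, chosen after they were seen, were 0, 0 and 1 in sham Balb/cJ, 69, 32 and 76 in TAC Balb/cJ, 38, 73 and 43 in sham Balb/cByJ, and 42, 56 and 113 in TAC Balb/cByJ, so sham Balb/cJ held the low values, as it did for the atrial genes. Of the 34 lists 14 passed camera, and 0 passed with an estimated correlation or by fry. The 8 lists that passed camera in a single strain had interaction medians of 0.25 (ribosomal proteins), 0.40 (endothelial markers), 0.08 (glycolysis), 0.18 (angiogenesis), -0.53 (mast cell markers), 0.26 (lymphocyte markers), 0.22 (smooth muscle markers) and 0.23 (Schwann cell markers), with adjusted p of 0.537 to 0.713 with an estimated correlation. The heat shock and unfolded protein list passed camera in both strains but in opposite directions. Its median was 0.20 in Balb/cJ (camera adjusted p = 0.0744) and -0.14 in Balb/cByJ (camera adjusted p = 0.0203). With an estimated correlation these were adjusted p = 0.593 and 0.646. Its interaction median was -0.37 (camera adjusted p = 1.23e-06, and adjusted p = 0.537 with an estimated correlation). Cell cycle genes had an interaction median of -0.90 (adjusted p = 0.537 with an estimated correlation). Igkc, which passed in Balb/cByJ, had an interaction of 2.38 ± 0.71 (limma adjusted p = 0.636). Larger effects in 1 strain's counts of calls are therefore not shown to differ between the strains at single genes, and the count of calls ranged from 0 to 4 when single libraries were left out. It was 0 without sham Balb/cJ 2, sham Balb/cByJ 2 or TAC Balb/cByJ 5, 2 without TAC Balb/cJ 4 or TAC Balb/cJ 5, 3 without TAC Balb/cJ 6 or sham Balb/cByJ 1, 4 without sham Balb/cByJ 3 and 4 without TAC Balb/cByJ 4, and 1 without the library labelled TAC Balb/cByJ 6, where 16 lists passed camera.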

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

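The tests of atrial tissue, of the strain genes of 1 library and of other splits of the libraries were all chosen or had their predictions written after the results were seen, while the interaction was planned.

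The interaction between strain and surgery passed limma at 1 gene, Prss35, whose effect of TAC differed by -5.10 (Balb/cByJ minus Balb/cJ). Gene lists passed camera for a difference between the strains in the effect of TAC at 14 of 34 lists, given here as median log2 differences, Balb/cByJ minus Balb/cJ. Lower medians were found for matrix and fibrosis genes (-0.24), cell cycle genes (-0.90), immediate-early genes (-0.43), heat shock and unfolded protein genes (-0.37), cytokine and inflammation genes (-0.28), sex-linked genes (-0.43), macrophage markers (-0.21), atrial markers (-1.36), adipocyte markers (-1.48) and mesothelial markers (-1.01). Higher medians were found for oxidative phosphorylation subunits (0.21), ribosomal proteins (0.25), endothelial markers (0.40) and erythroid markers (0.71). None passed with an estimated correlation (adjusted p = 0.537 or 0.702) or by fry. The sex-linked genes, included only to check the sex of the hearts, passed camera too.

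Other splits of the libraries into groups of the same sizes were fitted in the same way. With 10 splits of 6 libraries the share cannot fall under 0.05, as the lowest possible is 0.1. For TAC in Balb/cJ, 1 of 10 splits, the real one, gave as many genes as the real split (4419, highest other 2), and for lists 3 did (22, highest other 23). For TAC in Balb/cByJ, 1 split gave as many genes (1765, highest other 7) and 1 as many lists (20, highest other 19). Between the sham groups, 1 split gave as many genes (1175, highest other 0) and 4 as many lists (15, highest other 19). After TAC, 3 splits gave as many genes as the strains did (1, highest other 12) and 9 as many lists (11, highest other 20). For the interaction, 9 of 100 splits, the real one included, gave as many genes (1, highest other 966) and 59 as many lists (14, highest other 22). In 7 of these splits the count of genes was over 3 times the real one. In all 7 the sham libraries kept their strain labels while TAC labels were exchanged, which carries the difference between the sham groups into the interaction. Such splits are not free of strain effects, so these shares cannot show whether chance accounts for the interaction calls. Chance stays open there. Up to 23 lists passed camera in a split that mixed the groups, so a camera call alone carries little weight here.

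Atrial genes were nearly absent from the sham Balb/cJ libraries, which entered the TAC comparison in Balb/cJ, the strain comparison after sham and the interaction. Over all 13 measured atrial markers, the sham groups differed by a median log2 of 1.67 (7 passed adjusted over the list alone), which argues against TAC as the whole cause, and TAC and sham in Balb/cJ by 2.58 (10 passed), which argues against low expression in Balb/cJ hearts as such. Unequal amounts of atrial tissue in the dissected hearts may be a source: highest and lowest of the 3 sham Balb/cByJ hearts differed by a median ratio of 10.1 over these markers, although single markers ranged from 1.15 to 194, where the median gene varied 1.21-fold. Myl7, an abundant marker, was at 4670, 14508 and 237 in these hearts. The atria are part of the heart and the labels do not say how hearts were dissected, so an effect of strain and surgery together stays open.

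Whether atrial tissue could be the whole source of the rise of matrix genes after TAC was tested with the log2 level of Myl7, Myl4 and Sln as a covariate. In Balb/cByJ the matrix median stayed at 1.19 against 1.24 and 42 of 63 members passed, which argues against it on the log scale only. With the linear covariate the genes of all kinds that passed in Balb/cByJ fell from 1765 to 170 (153 higher, 17 lower). In Balb/cJ the matrix median was 1.34 against 1.76 with the log-scale covariate, but 0 members passed by limma. The log-scale covariate nearly coincides with the TAC and sham groups there, so the sources cannot be told apart by it. With the linear covariate the matrix median in Balb/cJ was 1.59 and 56 passed. The second test, made after the first left the question open, compared the sham groups, which differ in atrial genes: the upper quartile of the matrix list's differences was 0.32, far below 1.76. It argues against atrial tissue as the whole source only if matrix levels in unloaded hearts are alike in the strains.

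The library labelled TAC Balb/cByJ 6 lay on the Balb/cJ side at 17 of 20 genes that separated the other 11 libraries by strain at least 2-fold, the exceptions being Cdh20, Dbh and Gria4, and at 28 of 38 genes with a gap of 1.5-fold. RNA of a Balb/cJ heart under this label may be a source, although it does not account for the exceptions. A mix of both strains in equal parts would put the 20 genes midway, and their median lay 7.47% of the way from the Balb/cJ to the Balb/cByJ level (quartiles 0.984 and 32.7), but the 4 genes higher in Balb/cJ lay further, Arl2bp at 16.6%, Otud3 at 29.0%, Cuzd1 at 53.0% and Edn3 at 56.5%, a share that Dnah17 at -0.295% and Zhx2 at 1.31% argue against, so no single share of Balb/cByJ RNA accounted for all. Of 38 genes that separated the sham Balb/cByJ from all Balb/cJ libraries, chosen without any TAC Balb/cByJ library, TAC Balb/cByJ 4 and 5 had 80.3% on the Balb/cByJ side and this library 6 genes, which argues against an effect of TAC as the whole cause. Among libraries labelled Balb/cJ, TAC Balb/cJ 4 had the most genes on the Balb/cByJ side, 9 of 29 with the 2-fold and 23 of 64 with the 1.5-fold gap. The genes were chosen without the library tested, so genes that it alone kept out entered its set. It lay at 47 for Zhx2, 3 for Dnah17 and 213 for Otud3, where sham Balb/cByJ had 767 to 837, 805 to 1019 and 10 to 14. These values argue against it as a swap partner. No library labelled Balb/cJ lay on the Balb/cByJ side at most genes, and a single wrong label stays open.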

How the results depend on the processing

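Total rescaling, the atrial covariates and a replicate block for the TAC libraries were chosen after the data were seen, and the other alternatives were planned. The planned count models, their scalings and their filter were not run, as the values were not counts. Under the choices planned 2182 values of named genes kept direction and side of the threshold and 382 kept direction only, and for gene lists these were 1072 and 79. Under the added ones they were 383, 190 and 7 reversed for genes, and 223, 25 and 9 for lists. By the test's own direction, the 16 reversals of named genes and lists came with an atrial covariate. Some list medians near 0 changed sign with total rescaling while camera's direction, which is relative to other genes, did not, such as the contraction list in Balb/cJ (0.05). Where a value changed, the cause was not tested unless stated.

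At an adjusted p under 0.05, a stricter limit by construction, the counts were 2881 for TAC in Balb/cJ, 465 for TAC in Balb/cByJ, 568 between the sham groups, 0 between the TAC groups (1371 at an unadjusted p under 0.05) and 0 for the interaction (954 at an unadjusted p under 0.05), with 280 shared rises and 55 shared falls. Without a filter on low values 2 genes passed between the TAC groups, 0 for the interaction by limma, and 281 falls were shared. With voom 0 genes passed between the TAC groups and 0 for the interaction, and 9 lists passed between the sham groups. With a pseudocount of 5 the interaction had 0 genes by limma. In fits of only the 2 groups compared, TAC in Balb/cByJ had 2848 genes and the TAC groups 0. With total rescaling the interaction had 0 genes by limma, and 1191 rises and 117 falls were shared. With an estimated correlation 0 lists passed camera in each of the 5 comparisons, and with fry 13 passed for TAC in Balb/cByJ, 2 between the sham groups, 0 between the TAC groups and 0 for the interaction.

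With the log-scale atrial covariate 0 genes passed for TAC in Balb/cJ by limma (1431 at an unadjusted p under 0.05), 694 for TAC in Balb/cByJ, 35 between the sham groups, 0 between the TAC groups and 0 for the interaction, with 0 shared rises and 0 shared falls. Acads was at -0.40 for TAC in Balb/cJ and -0.48 between the sham groups, neither passing, and 14 lists passed for TAC in Balb/cJ. With it, in TAC against sham in Balb/cJ, Bmp10 (-2.36), Hamp (-2.01), Myl4 (-1.40), Cidec (-0.14) and Adipoq (-0.12) reversed, as did the lists of interferon response (-0.17), atrial markers (-0.83) and adipocyte markers (-0.16); the contraction list, at a median of -0.01, reversed in camera's direction. Between the sham groups Hamp (-1.65), Myl4 (-1.33), atrial markers (-0.56) and adipocyte markers (-2.15) reversed, and in the interaction atrial (1.05) and adipocyte markers (2.38). For the atrial genes the covariate holds them by construction.

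With the linear atrial covariate 170 genes passed for TAC in Balb/cByJ, where the atrial list reversed (-0.36), 0 between the TAC groups and 7 for the interaction; 17 lists passed between the TAC groups, and 125 rises and 12 falls were shared.

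Leaving out each library in turn gave 2156 to 5038 genes for TAC in Balb/cJ, 6 to 2321 for TAC in Balb/cByJ, 321 to 1606 between the sham groups, 0 to 75 between the TAC groups and 0 to 4 for the interaction, with 6 to 980 shared rises and 0 to 629 shared falls. The Acads difference ran from -0.70 to -0.36, -0.24 to -0.12, -0.69 to -0.55, -0.41 to -0.07 and 0.20 to 0.53 in the same order of comparisons, and the lists passing camera from 20 to 24, 19 to 21, 12 to 20, 9 to 17 and 14 to 19.

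The planned replicate block, by the numbers of the titles, was possible only for the sham libraries, since the TAC columns carry other numbers. It gave 984 genes (580 higher, 404 lower), an Acads difference of -0.60 and 21 lists, and it changed no call of these summaries. Same-numbered sham libraries correlated at r = -0.21, -0.07 and 0.17 in their deviations across genes, and not every library correlated best with its own number. These values gave no sign of a pairing by number but cannot exclude it. A replicate block by the column numbers of the TAC libraries, 4 to 6, gave 0 genes between the strains after TAC, an Acads difference of -0.22 and 12 lists. Same-numbered TAC libraries correlated at r = 0.06, 0.10 and -0.05, and library 6 of neither strain correlated best with its own number. A pairing of the TAC libraries by number was thus not seen across genes but stays open. Pdk4, Ucp3 and Angptl4 were lowest in library 6 of both TAC groups, as given below. With few genes changed, of simulated 1.5-fold changes 34.3% were recovered for TAC in Balb/cJ and 31.3% for TAC in Balb/cByJ.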

Other observations

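The tests of the PPAR alpha targets and of genomic clustering were chosen after the results were seen, and so were the genes named here.

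Igf1, a growth factor secreted by macrophages and fibroblasts, rose in both strains. Its normalized values were 148, 139 and 123 in sham Balb/cJ and 592, 521 and 633 in TAC Balb/cJ, and 151, 235 and 175 in sham Balb/cByJ and 581, 553 and 604 in TAC Balb/cByJ. The rise was 2.08 ± 0.15 in Balb/cJ (limma adjusted p = 0.000115) and 1.65 ± 0.15 in Balb/cByJ (adjusted p = 0.00166), and the interaction of -0.43 ± 0.22 did not pass (adjusted p = 0.738). Igf1 did not pass in Balb/cJ with the log-scale atrial covariate (1.93).

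Pdk4, a kinase that shuts off pyruvate oxidation, Ucp3, a mitochondrial carrier, and Angptl4 were lowest in library 6 of each TAC group. Pdk4 was at 30649, 19501 and 1593 in TAC Balb/cJ libraries 4 to 6 and at 35375, 44695 and 4652 in the libraries labelled TAC Balb/cByJ 4 to 6. Ucp3 was at 504, 851 and 69 and at 1739, 3165 and 565 in the same order, and Angptl4 at 294, 279 and 57 and at 1297, 2022 and 152. In sham libraries Pdk4 ranged from 9608 to 14612 in Balb/cJ and from 40975 to 47744 in Balb/cByJ. Pdk4 and Ucp3 did not pass limma in the TAC comparisons (adjusted p = 0.836 and 0.438 in Balb/cJ, 0.454 and 0.607 in Balb/cByJ).

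Angptl4, a target of PPAR alpha, was higher in sham Balb/cByJ hearts, which could reflect a rise of the targets of PPAR alpha as a group. The upper quartile of the differences over the list of 34 targets was 0.33, which argues against a rise of the whole group by as much as Angptl4.

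Genes that separate the strains at least 1.5-fold might lie together in genomic segments that differ between the substrains. Of 38 such genes 3 (Glo1, Dnah8 and Gm10503) had another within 1000000 bases, where 10000 random draws gave a median of 2 and a 95th percentile of 6, and a share of 0.326 of the draws gave as many. Clustering beyond chance was thus not found over the 38 genes as a set. The gap had to hold between all libraries except the one labelled TAC Balb/cByJ 6, which left out genes with smaller strain differences. This count therefore cannot exclude shared segments, among them a single segment of few genes. The 3 genes lie on chromosome 17 between 30592861 and 30963214. Btbd9, beside them at 30215524 to 30576287, had a gap just under 1.5-fold and was not counted. It was at 645 to 741 in Balb/cJ libraries, 647 in the library labelled TAC Balb/cByJ 6, and 1107 to 1371 in the other Balb/cByJ libraries. Anxa13, on chromosome 15 at 58341464 to 58389274, was lower in sham Balb/cByJ (-2.11 ± 0.43, limma adjusted p = 0.0213). It lay near Zhx2, at 57694667 to 57839832, but was not counted either.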
